A study of Bos taurus with 20 samples.

How the data were processed

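Gene expression was measured in liver of Holstein-Friesian dairy cows on Affymetrix bovine gene arrays, with 1 biotin-labelled array per sample. The 20 arrays came from 10 cows, 5 per diet, each sampled before and after calving. During the last 4 weeks of the dry period, the time before calving in which a cow is not milked, the ration held 0.16% phosphorus of dry matter (low phosphorus, LP) or 0.35% (adequate phosphorus, AP). From calving on, all cows received the same ration, per the labels' protocols. Groups were taken from the diet and time labels. The 4-digit number in each sample title was read as the animal's number, because each number occurs once antepartum and once postpartum within 1 diet. Cows are named here by letter, A to E in LP and F to J in AP, in the order of the labels.

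The authors deposited a log2 signal for each of 24333 probe sets and each array. SST-RMA is named in the deposited workbook, and RMA and Affymetrix Expression Console 1.4 are named in the submitters' processing notes. RMA places all arrays on nearly 1 distribution, so that the median signal per array lay between 5.97 and 6.14 and a shift of all genes together cannot be seen in these values. The authors also deposited a log2 ratio, a signed fold change and an unadjusted paired p-value of postpartum against antepartum for each probe set. Recomputing these from the 20 array columns gave the same ratios to within 4.44e-16 and the same p to within 3.7e-12, with arrays paired by animal number. A second deposited table held the same log2 signals, rounded, with a largest difference of 0.005. No detection call was used, and the genome build of the workbook's coordinates is not given in the sources used here.

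A gene was a symbol that the workbook gives to a probe set alone, which held for 20421 probe sets and 20011 genes. Another 3912 probe sets without a symbol, 1136 of them marked as cross-hybridizing, were left out. For the 386 symbols with more than 1 probe set, the probe set with the highest mean over all arrays was used. Names were compared with a reference table of assembly ARS-UCD2.0, used for names only. By accession 14476 genes matched, by symbol 3663 and by synonym 76, and 1796 did not. Some symbols had been turned into dates by a spreadsheet program before deposition. These were kept as given, and none is named here. No filter on dim genes was used.

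Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on 4 group means over all 20 arrays, two-sided, with Benjamini-Hochberg adjustment over 20011 genes and a threshold of 0.05. The 7 comparisons of genes were LP against AP antepartum, postpartum and over both times, postpartum against antepartum over both diets and within each diet, and the diet by time interaction. Over both times, each animal entered once, as the mean of its arrays. A fold change is 2 to the power of the log2 difference. The number of arrays, 5 per group, limits the precision. The median standard error of a log2 difference was 0.14 within 1 time or 1 diet, 0.099 for time over both diets and 0.198 for the interaction.

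The samples, groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 38 lists (24 pathway lists and 14 cell type marker lists, 895 distinct genes) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, in 4 comparisons. Named genes were, per comparison and direction, the 5 with the largest change among those that passed and moved the same way in every animal. Symbols that start with LOC were left out. Where fewer than 5 passed, genes of lowest unadjusted p filled the 5 and are said not to pass. From described lists, up to 2 members per direction that passed were added, or the 2 of lowest p. Some genes that this rule selects are not reported here. A Gene Ontology enrichment of the genes that passed for time, by a one-sided exact test over 10192 annotated genes and 725 terms, was chosen after the gene results were seen.

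Same-numbered samples come from the same animal, so the numbers pair the arrays. Residuals from the group means correlated across genes with a median r of 0.167 between arrays of the same animal (0.072 to 0.312, over 0.1 in 8 of 10 animals) and of -0.017 between animals. The test without the animal was kept as planned, and the fit with the animal as a block was run beside it. Other alternatives were quantile normalization, median centring, filters on dim genes, the mean of a gene's probe sets, every probe set, a trended robust variance, array weights, only the groups compared, array number as a covariate, the rounded table, other list tests, an unadjusted threshold with 1.5-fold, and leaving out each animal.

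The same code was tested on simulated data for 20011 genes with known changes. At 2-fold it recovered 92.5% of changed genes for diet antepartum, 94% for diet postpartum, 97% for diet over both times, 94% for time and 71.6% for the interaction. At 1.5-fold it recovered 46.3% for diet antepartum, 56.7% for diet postpartum and 16.4% for the interaction. Each set with changes held 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, more than passed in the real diet comparisons. So many changes ease the adjusted threshold, and the arrays of a cow were drawn as independent. In the real arrays, some differences above 2-fold did not pass. The rates are therefore not the power of the real comparisons. Simulated time data with no change gave 0 calls by limma, and the sets with changes gave between 6 and 11 false calls. Of 3 lists shifted in simulated time data camera called 3, and of 31 lists without shifted genes it called 0. Simulated genes were drawn independently of each other. These list counts therefore do not measure false calls where the genes of a list move together. In the real arrays, other splits for time called a median of 13 lists.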

Results

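Liver of 10 Holstein-Friesian cows was profiled before and after calving, with 5 cows on the low phosphorus ration (LP) and 5 on the adequate one (AP) and n = 5 arrays in each of the 4 groups. The comparisons ask what restricted dietary phosphorus before calving did to liver expression, whether a difference remained once all cows had the same ration, and how the liver changed from late pregnancy to lactation. Values are log2 signals, so that a difference of 1 is a 2-fold change. The postpartum LP array of cow C stood apart from the other arrays. It alone spanned the first principal component, with 24.8% of the variance and a score of 85.8, and it held the highest adipocyte, fibroblast and skeletal muscle marker scores of all arrays. Skeletal muscle markers were also high in the antepartum AP array of cow F, with a score of 1.72 against 0.22 in the next array of its group.

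**Figure D1:**
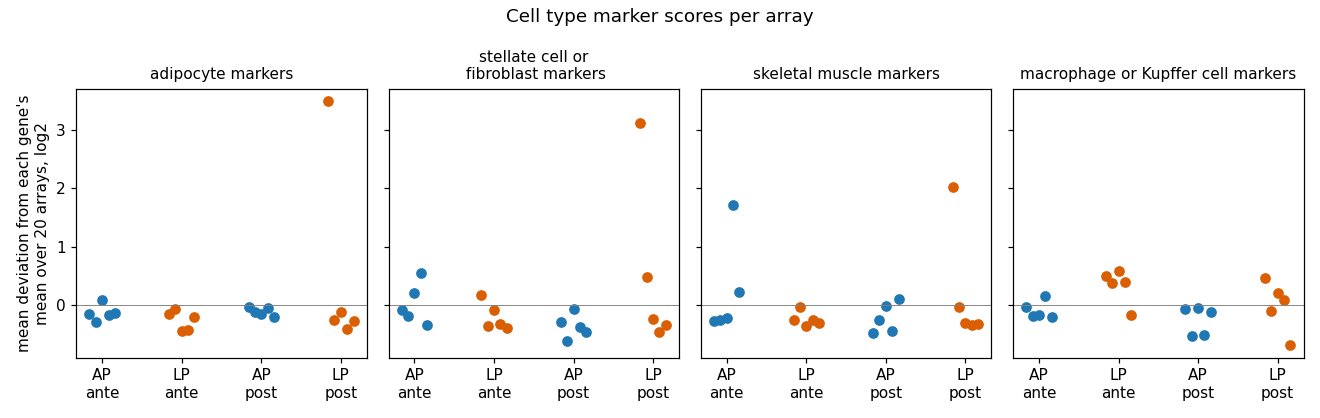
Mean deviation of each array's marker genes from their mean over 20 arrays (vertical axis, log2) for 4 cell types, with 1 point per array (blue AP, orange LP) and groups along the horizontal axis. The highest adipocyte (3.5), fibroblast (3.12) and muscle (2.02) points are all the postpartum LP array of cow C.

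HP, which encodes the hemoglobin-binding acute phase protein haptoglobin, rose 12.9-fold across calving over both diets (log2 difference 3.69, SE 0.42, limma adjusted p = 9.47e-05, higher in 10 of 10 cows). Its mean was 8.15 ± 1.68 (SD, n = 5) antepartum and 12.50 ± 0.31 postpartum in AP, and 9.25 ± 1.14 and 12.28 ± 0.60 in LP. GPX3, encoding a secreted glutathione peroxidase, rose 12.3-fold (SE 0.522 log2, adjusted p = 0.0011, 9 of 10 cows). IGF1, the growth factor made by the liver under growth hormone, was 4.09-fold lower (log2 difference -2.03, SE 0.258, adjusted p = 0.000305, 9 of 10 cows).

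In all, 300 of 20011 genes passed, 140 higher and 160 lower postpartum, of which 20 and 25 changed at least 2-fold. At an unadjusted p under 0.05 there were 2372, against 1001 by chance. The largest increases shared by all 10 cows, after HP, were in SAA3 (3.82-fold, SE 0.33), C5H12orf75 (3.08-fold, SE 0.179), APOA1 (2.48-fold, SE 0.132) and LDHB (2.46-fold, SE 0.113, adjusted p = 3.46e-06). SAA3 encodes a serum amyloid A, APOA1 the main protein of high density lipoprotein and LDHB a lactate dehydrogenase subunit. Large decreases shared by all cows were in CGN1, encoding the collectin conglutinin (5.15-fold, SE 0.289), SCGB1D (3.59-fold, SE 0.307), PPP1R3C, a glycogen-targeting phosphatase subunit (3.37-fold, SE 0.228), and RNF125 (2.92-fold, SE 0.229). The authors' deposited table gave HP a log2 ratio of 3.69 and an unadjusted paired p of 5.65e-05, and 83 of its probe sets passed after adjustment of its p. The count of 300 was 156 without cow F, 163 without cow H, 131 without cow I, 138 without cow D, 150 without cow J and 140 without cow E. It was 546 without the postpartum array of cow C, and 296 of the 300 were among these.

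**Figure D2:**
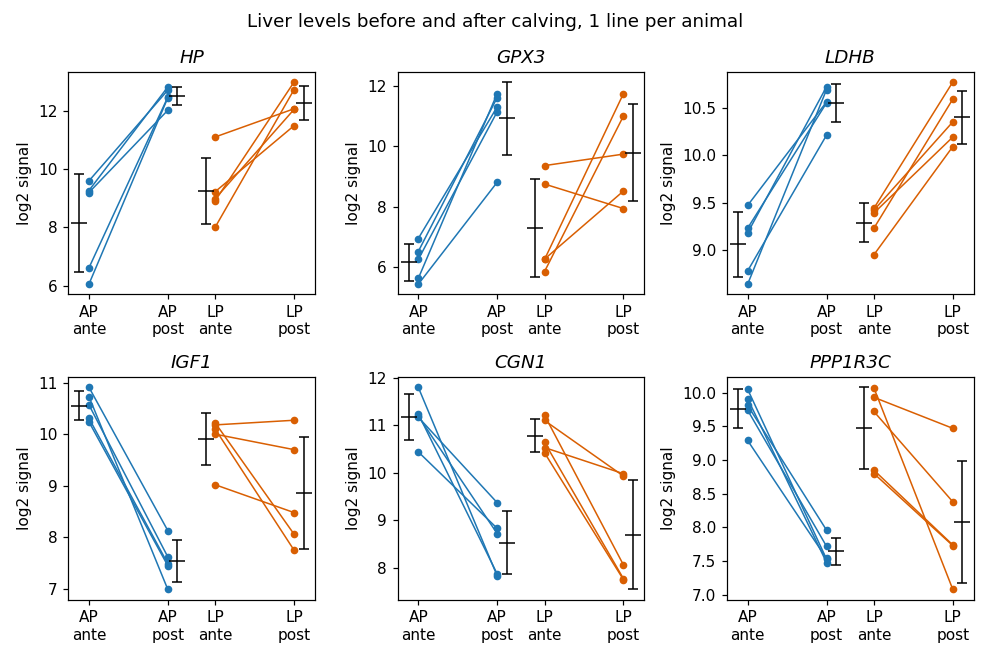
Log2 signal (vertical axis) of 6 genes before and after calving, with 1 line per cow (blue AP, orange LP) and black bars for the mean and SD of 5 cows. HP and LDHB rise and CGN1 and PPP1R3C fall in 10 of 10 cows, and GPX3 rises and IGF1 falls in 9 of 10.

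Of 31 positive acute phase genes, 9 rose and 1 fell after calving, and 14 and 1 passed adjusted over the list alone. The gene that fell was CD14, a lipopolysaccharide co-receptor (1.4-fold, SE 0.123 log2, adjusted p = 0.0497), which passed in 9 of 25 settings, with an adjusted p of up to 0.16. The list was shifted upward by camera (adjusted p = 5.81e-12; adjusted p = 0.447 with an estimated correlation). Of 12 negative acute phase genes, 5 fell and 1 rose (7 and 2 adjusted over the list alone). IGF1 and TTR, the thyroxine carrier transthyretin (1.52-fold, SE 0.107), fell, while APOA1, also on this list, rose. Its camera adjusted p was 4.58e-05 (adjusted p = 0.447 with an estimated correlation). Acute-phase response was the only Gene Ontology term that passed, with 6 of its 13 genes among the higher ones against 0.12 expected (adjusted p = 1.16e-06, exact test). These were HP, ITIH4, LBP, LOC104968478, ORM1 and SAA3.

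Growth hormone and insulin signalling genes went both ways, with 3 of 25 higher and 5 lower (5 and 5 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.28). GHR, the growth hormone receptor, fell by 0.95 log2 (SE 0.125, adjusted p = 0.000387), and IGFALS fell by 1.05 (SE 0.187, adjusted p = 0.00568). IGFBP1 rose by 1.16 (SE 0.26, adjusted p = 0.024) and IGFBP2 by 0.78 (SE 0.17, adjusted p = 0.0186). These 4 genes were chosen after their values were seen. GHR and IGFALS passed in all 16 fits run on them, IGFBP1 in 12 (adjusted p up to 0.0918 without cow E) and IGFBP2 in 11 (up to 0.0795 without cow D).

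Among 22 gluconeogenesis genes 2 rose and 0 fell by limma (4 and 0 adjusted over the list alone). They were LDHB and PC, encoding pyruvate carboxylase (2.32-fold, SE 0.229, adjusted p = 0.00815). In the fatty acid oxidation list, 3 of 45 rose and 0 fell by limma (10 and 1 adjusted over the list alone), including ANGPTL4, an inhibitor of lipoprotein lipase (1.94-fold, SE 0.187), and CPT1B (1.83-fold, SE 0.181). Of 30 fatty acid synthesis genes 3 fell and 0 rose by limma (8 and 0 adjusted over the list alone), among them THRSP, a regulator of lipogenesis (2.53-fold, SE 0.32), and GPAM (1.48-fold, SE 0.118). Camera gave these lists adjusted p of 0.00201, 0.000517 and 0.000359, and for each the adjusted p = 0.516 with an estimated correlation. In the urea cycle and amino acid list HAL, the histidine-degrading enzyme, rose 2.44-fold (SE 0.269) and OTC, of the urea cycle, fell 1.72-fold (SE 0.198), with 4 up and 3 down adjusted over the list alone and no shift (camera adjusted p = 0.713). Of the phosphate genes, ANKH, a pyrophosphate transport regulator, rose 1.43-fold (SE 0.127) and ENPP1, which makes pyrophosphate, fell 1.34-fold (SE 0.103); 1 up and 2 down passed adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.0798). RGN, encoding a calcium-binding protein, was the 1 vitamin D and calcium gene that passed, down 1.4-fold (SE 0.113; 1 adjusted over the list alone; camera adjusted p = 0.834).

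Bile acid genes fell in 4 of 25 cases and rose in 0 by limma (6 and 1 adjusted over the list alone), led by NR0B2, the bile acid responsive repressor SHP (2.4-fold, SE 0.262), and ABCG8, a sterol exporter (2.34-fold, SE 0.214). Xenobiotic and steroid genes fell in 7 of 34 cases (13 adjusted over the list alone), led by CYP26A1, which clears retinoic acid (2.39-fold, SE 0.225), and HSD17B2 (1.99-fold, SE 0.233). Camera adjusted p were 0.00113 and 9.9e-09 (adjusted p = 0.516 with an estimated correlation for both). Of 38 cell cycle genes 36 had a positive difference, yet 0 rose by limma over all genes tested, against 23 adjusted over the list alone (camera adjusted p = 4.71e-17; adjusted p = 0.447 with an estimated correlation). The 1 that passed was CDKN1A, an inhibitor of the cycle, which fell 1.5-fold (SE 0.126). The rise of the list was uneven between cows. Its mean score per array went from -0.10 to 1.24 in cow G and from -0.30 to 0.65 in cow H. It hardly changed in cow D (-0.27 to -0.26) and cow E (-0.09 to -0.08) and fell in cow J (-0.31 to -0.38).

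Interferon genes had 34 of 44 positive differences, with XAF1 up 1.28-fold (SE 0.083; 4 adjusted over the list alone; camera adjusted p = 6.65e-08). The 67 oxidative phosphorylation genes had 50 positive, and 0 passed over all genes by limma (4 adjusted over the list alone; camera adjusted p = 5.47e-06). The lowest p were those of NDUFV2 (1.26-fold, adjusted p = 0.0644, and 0.0345 with the animal as a block) and COX5A (1.22-fold, adjusted p = 0.0931). Unfolded protein response genes had 22 of 33 positive and 0 passing by limma, 0 also adjusted over the list alone (camera adjusted p = 0.012). In the NRF2 list 3 rose and 1 fell (8 and 4 adjusted over the list alone), with GPX3 and SRXN1 (1.42-fold, SE 0.115) up and GSTM2 (1.79-fold, SE 0.203, adjusted p = 0.0379, and 0.0515 with the block) down. Its camera adjusted p was 0.0434, and 0.0502 with the block. For these 4 lists the adjusted p = 0.516 with an estimated correlation. Complement and coagulation genes had 29 of 39 negative differences, with CFD, complement factor D, down 1.39-fold (SE 0.107; 1 adjusted over the list alone; camera adjusted p = 0.00589; adjusted p = 0.658 with an estimated correlation).

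Some cell type marker lists moved too, but those of hepatocytes share genes with the lists above. The hepatocyte list shares ALB, TTR, TF, APOA1 and AHSG with the negative acute phase list. The periportal list shares HAL, ASS1 and GLS2 with the urea cycle list, and the pericentral list shares CYP2E1 with the xenobiotic list. The movement of the hepatocyte, periportal and pericentral lists is therefore no separate evidence on cell types. The macrophage list shares no gene with the lists above. Macrophage markers were negative in 12 of 14 (camera adjusted p = 6.21e-05), with C1QC down 1.47-fold (SE 0.133; 6 adjusted over the list alone). Hepatocyte markers had 3 down and 1 up (5 and 1 adjusted over the list alone; camera adjusted p = 0.0138), where AHSG (1.35-fold, adjusted p = 0.048) had 0.0978 with the block. Pericentral markers, of hepatocytes near the central vein, had 2 down, LGR5 (2.04-fold, SE 0.19) and CYP2E1 (1.26-fold, SE 0.066), and 3 adjusted over the list alone (camera adjusted p = 0.0365, and 0.0616 with the block). Periportal markers had HAL up and CDH1, encoding E-cadherin, down 1.72-fold (SE 0.123; 2 and 1 adjusted over the list alone; camera adjusted p = 0.0192). All 4 of these lists had adjusted p = 0.516 with an estimated correlation. Adipocyte markers were at 0.0544 by camera and 0.0459 with the block, and T or NK cell markers at 0.0553 and 0.015. Without the block, these had adjusted p = 0.642 and 0.516 with an estimated correlation. With 1 cow left out, 7 calls were lost, with a highest adjusted p of 0.105 for the unfolded protein response and 0.081 for periportal markers (without cow B), 0.179 for NRF2 (without cow B; kept in 5 of 10 fits), and 0.143 for bile acid, 0.515 for complement, 0.115 for hepatocyte and 0.199 for pericentral lists (without cow C). Without the postpartum array of cow C, bile acid (camera adjusted p = 0.0874), complement (0.355), hepatocyte (0.0924) and pericentral lists (0.0874) were not called. Cholesterol synthesis (0.00322) and lipoprotein lists (0.0081) were then called upward, and fibroblast (0.0102) and skeletal muscle markers (0.0337) downward. For these 4 lists in that fit the adjusted p = 0.582, 0.245, 0.579 and 0.654 with an estimated correlation. The skeletal muscle score fell from 1.72 to -0.43 in cow F, whose antepartum array was high in these markers. In the other cows with both arrays in that fit it moved far less, so the muscle call leans on 1 array.

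No shift by camera was found for NF-kB and cytokine genes (adjusted p = 0.108), lipoprotein genes (0.262), cholesterol synthesis (0.464), ketone body metabolism (0.586), glycolysis and glycogen (0.586), purine metabolism (0.707) or iron and heme genes (0.834). The same held for cholangiocyte (0.314), erythroid (0.449), fibroblast (0.626), B or plasma cell (0.713), neutrophil (0.834), endothelial (0.834), platelet (0.947) and skeletal muscle markers (0.964). Of the genes named for time, HP, SAA3, C5H12orf75, APOA1, LDHB, GPX3, PC, ANGPTL4, IGF1, CGN1, SCGB1D, PPP1R3C, RNF125, ABCG8, CYP26A1, LGR5, CYP2E1, CDH1 and TTR passed in every setting run. These were 23 settings for C5H12orf75 and 24 for LGR5, as filters on dim genes removed them in the rest. Antepartum levels of C5H12orf75 ran from 3.93 to 4.92, near or below the lower quartile of the arrays. Besides CD14, the call was lost in some for AHSG (passed in 11 of 25), OTC (15), XAF1 (15 of 24), GSTM2 (16), ANKH, THRSP, C1QC and HSD17B2 (17 each), RGN and ENPP1 (18 each), CFD and SRXN1 (19 each), CDKN1A (20), HAL and CPT1B (21 each), GPAM (22) and NR0B2 (23). In all, 17 of 38 lists were called for time, 9 upward and 8 downward, and 0 with an estimated correlation or with limma's fry.

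In AP cows alone, GPX3 rose 27.1-fold (SE 0.739 log2, adjusted p = 0.00376), HP 20.5-fold (SE 0.594, adjusted p = 0.000966), SLC13A5, a citrate transporter, 14.0-fold (SE 0.579, adjusted p = 0.00361) and SAA3 5.56-fold (SE 0.467), each in 5 of 5 cows. IGF1 fell by 3.02 log2 (SE 0.364, adjusted p = 0.000322), and lower too were CGN1 (-2.65 log2, SE 0.409), THRSP (-2.30, SE 0.453), SCGB1D (-2.23, SE 0.433) and PPP1R3C (-2.11, SE 0.323). HP, SLC13A5, C5H12orf75 and IGF1 passed in every setting run, which for C5H12orf75 did not include the filters on dim genes. With 1 cow left out, the adjusted p rose to 0.0652 for GPX3 (without cow J), 0.113 for SAA3 (cow J), 0.0789 for CGN1 (cow I), 0.154 for THRSP (cow F), 0.172 for SCGB1D (cow I) and 0.0548 for PPP1R3C (cow H). In total 83 genes passed, 50 higher and 33 lower (1842 unadjusted), and 126 did with the animal as a block. The count was 16 without cow F, 54 without cow G, 13 without cow H, 13 without cow I, 13 without cow J and 243 without cow C, which is an LP cow and enters through the shared spread.

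In LP cows alone, LDHB rose 2.16-fold (SE 0.16, adjusted p = 0.0151) and APOA1 2.31-fold (SE 0.187, adjusted p = 0.0217), and SYNJ2, encoding an inositol phosphatase, fell by 0.77 log2 (SE 0.124, adjusted p = 0.0269, and 0.141 with the animal as a block). These were all 3 genes that passed (1192 unadjusted). With 1 cow left out, the adjusted p rose to 0.182 for LDHB (without cow E) and to 0.354 for APOA1 and 0.4 for SYNJ2 (without cow D). HP was 8.13-fold higher (SE 0.594, 5 of 5 cows) and CGN1 4.23-fold lower (SE 0.409) without passing (adjusted p = 0.142 for both), as was SSR4, 1.88-fold higher (adjusted p = 0.0827). The count was 0 without cow A, cow D or cow E, 1 without cow I, 6 without cow B, and 9 without the postpartum array of cow C. All 83 genes called in AP had the same sign in LP, where 2 of them passed, and the median ratio of LP to AP change was 0.517. The difference itself was tested as the interaction, where 0 genes passed by limma (559 unadjusted; 0 with the block).

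Before calving, when the rations differed, SYT4 was the only gene that passed. SYT4, encoding the vesicle protein synaptotagmin 4, was 1.78-fold higher in LP than in AP (log2 difference 0.83, SE 0.117, limma adjusted p = 0.0109, 5 of 5 LP cows above the AP mean). Its means were 8.60 ± 0.25 (SD, n = 5) in LP and 7.78 ± 0.09 in AP. The workbook places its probe set 12808553 on chromosome 24 from 12950391 to 12960189, on a genome build not given in the sources used here. At an unadjusted p under 0.05 there were 490 genes, against 1001 by chance. SYT4 had an adjusted p of 0.0617 without cow A, 0.0985 without cow F, 0.0922 without cow G, 0.104 without cow I, 0.12 without cow D and 0.167 with only the groups compared.

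**Figure D3:**
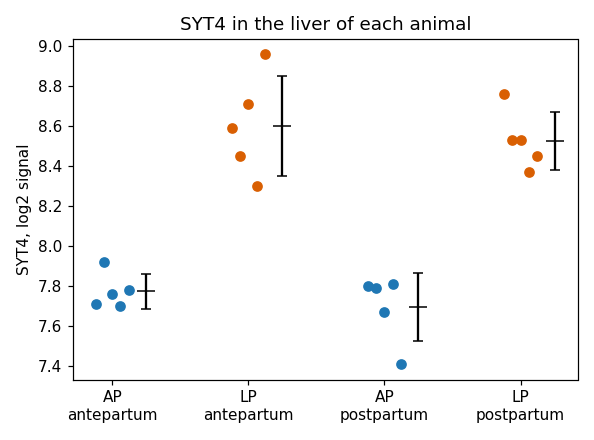
Log2 signal of SYT4 (vertical axis) in each of 20 arrays by group (horizontal axis), with black bars for the mean and SD of 5 cows. LP means are 8.60 and 8.53 and AP means 7.78 and 7.70.

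Macrophage markers were higher in LP before calving for 14 of 14 genes (median 0.44 log2, camera adjusted p = 3.83e-13; adjusted p = 0.144 with an estimated correlation). None passed over all genes; 2 did adjusted over the list alone, with C1QB 1.42-fold (SE 0.158) and C1QA 1.43-fold (SE 0.172) higher. T or NK cell markers were higher for 17 of 18 (median 0.17, camera adjusted p = 1.06e-06; adjusted p = 0.144 with an estimated correlation), with KLRK1 1.92-fold (SE 0.338). Interferon genes were positive in 37 of 44 (IRF9 1.26-fold; camera adjusted p = 5.73e-05) and positive acute phase genes in 24 of 31 (SAA4 1.89-fold; 0.000137), both with adjusted p = 0.826 with an estimated correlation. NF-kB genes were positive in 21 of 35 (ICAM1 1.39-fold, IL1A 1.35-fold; camera adjusted p = 0.000137; adjusted p = 0.558 with an estimated correlation), with 3 adjusted over the list alone. Oxidative phosphorylation genes were positive in 46 of 67 (CYCS 1.41-fold; 0.024), with adjusted p = 0.978 with an estimated correlation, and endothelial markers in 9 of 13 (CLEC4G 1.19-fold; 0.0441), with adjusted p = 0.832 with an estimated correlation. Whichever cow was left out, the first 5 of these lists kept the call, oxidative phosphorylation did in 5 of 10 fits (up to 0.372, without cow G) and endothelial markers in 3 (up to 0.252, without cow H).

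Lower in LP before calving were xenobiotic genes, negative in 27 of 34 (SULT1E1 2.54-fold, CYP26A1 1.66-fold; camera adjusted p = 0.00076; adjusted p = 0.839 with an estimated correlation). Cholesterol synthesis genes were negative in 21 of 24 (camera adjusted p = 0.00158; adjusted p = 0.978 with an estimated correlation) and fatty acid synthesis genes in 26 of 30 (GPAM 1.29-fold; 0.0295; adjusted p = 0.843 with an estimated correlation). Skeletal muscle markers were negative in 12 of 13 (MYH1 1.72-fold; 0.00017) and erythroid markers in 7 of 13 (HBA 1.65-fold; 0.0441), each with adjusted p = 0.826 with an estimated correlation. Xenobiotic genes kept the call whichever cow was left out. Cholesterol synthesis was lost without cow A (0.451) and cow G (0.26), and fatty acid synthesis was kept in 6 of 10 fits (up to 0.372, without cow G), skeletal muscle in 9 (0.626 without cow F) and erythroid markers in 3 (up to 0.348, without cow F). Without the postpartum array of cow C, fibroblast markers were called downward (camera adjusted p = 0.000677; adjusted p = 0.591 with an estimated correlation) and endothelial (0.0657) and erythroid markers (0.0682) were not called, and skeletal muscle markers were not (0.294) when the antepartum array of cow F was left out as well. The antepartum array of cow F also had the highest antepartum fibroblast score, 0.56 against 0.21 in cow G, the next of its group. The fibroblast call thus leans in part on that array. Except where given, 0 members of the lists named here passed by limma, over all genes or adjusted over the list alone. Phosphate genes showed no shift (camera adjusted p = 0.382), with SLC17A2 1.31-fold lower and SLC20A1, a phosphate importer, 1.26-fold higher, neither passing (unadjusted p = 0.0462 and 0.0805 by limma). Nor did vitamin D and calcium (0.382), urea cycle (0.192), fatty acid oxidation (0.866) and gluconeogenesis genes (0.954). In all 12 of 38 lists were called, 7 upward and 5 downward, and 0 with an estimated correlation or fry.

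After calving, on the shared ration, SYT4 was again 1.78-fold higher in LP (log2 difference 0.83, SE 0.117, limma adjusted p = 0.0105, 5 of 5 LP cows above the AP mean), with means of 8.53 ± 0.15 (SD, n = 5) and 7.70 ± 0.17. These are the same 10 cows as before calving, so that the results at both times are not independent. No other gene passed, with 1132 at an unadjusted p under 0.05. IGF1 was 2.49-fold (SE 0.364) and THRSP 2.79-fold (SE 0.453) higher in LP, and MAP2 2.18-fold (SE 0.24) and HAL 2.17-fold (SE 0.381) lower, each in 5 of 5 cows without passing (adjusted p = 0.812). SYT4 had an adjusted p of 0.0752 without cow C, 0.0932 without cow G, 0.108 without cow H, 0.0516 without cow I, 0.0749 without cow D and 0.213 with only the groups compared, and 2 genes passed without cow B. Over both times, on animal means, SYT4 was 1.78-fold higher in LP (SE 0.089, adjusted p = 0.00985) and again alone (728 unadjusted), with 0.0521 without cow F, 0.0588 without cow G, 0.0558 without cow H, 0.0568 without cow I and 0.0615 without cow D. Its limma adjusted p was 0.129 without the postpartum array of cow C and the antepartum array of cow F. Both cows then dropped out, as only cows with both arrays enter this comparison. Without these arrays the limma adjusted p was 0.067 postpartum. Over all settings the SYT4 difference stayed between 0.74 and 0.90 log2 antepartum, 0.76 and 0.88 postpartum and 0.80 and 0.89 over both times.

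Camera called 19 of 38 lists postpartum, 5 upward and 14 downward in LP, but 5 without cow C and 5 without its postpartum array alone. Those lower were urea cycle and amino acid genes (38 of 40 negative, camera adjusted p = 2.69e-08), cell cycle (34 of 38, 1.37e-06), fatty acid oxidation (35 of 45, 3.56e-05), complement (36 of 39, 4.13e-05), gluconeogenesis (19 of 22, 0.000177), lipoprotein (20 of 24, 0.000256) and xenobiotic genes (29 of 34, 0.0012). Also lower were periportal markers (8 of 10, 0.00606), purine (22 of 32, 0.0117), iron (18 of 28, 0.033) and hepatocyte markers (10 of 12, 0.036). Higher were fibroblast (15 of 16 positive, 9.5e-06) and macrophage markers (12 of 14, 0.00884) and NF-kB genes (23 of 35, 0.0265). Each of these had adjusted p = 0.62 with an estimated correlation. Bile acid genes (18 of 25 negative, 0.00603), skeletal muscle markers (12 of 13 positive, 0.00603) and adipocyte markers (6 of 7 positive, 0.0379) had adjusted p = 0.64 with an estimated correlation, oxidative phosphorylation (48 of 67 negative, 0.0217) 0.69 and positive acute phase genes (24 of 31 negative, 0.0358) 0.664. In these lists 0 members passed by limma over all genes or adjusted over the list alone. Phosphate (0.112), vitamin D and calcium (0.642) and fatty acid synthesis genes (0.402) were not shifted. Without that array, the cell cycle list stayed lower (camera adjusted p = 6.76e-13) and fibroblast markers higher (0.0461), and cholesterol, interferon and T or NK cell lists were higher (0.0461 each), all 5 with adjusted p = 0.907 with an estimated correlation. With all arrays of the other cows, the cell cycle list was not called without cow G (camera adjusted p = 0.145), whose postpartum score of 1.24 was the highest in AP, against 0.65 in the next cow. Of the 19 lists, only the fibroblast list kept its call whichever cow was left out, at 0.0494 without cow C. Its mean difference of 0.869 log2 was 0.217 without the array of cow C. Lost without cows other than C, too, were purine (kept in 8 of 10 fits), xenobiotic (8), oxidative phosphorylation (7), iron (6), macrophage (5), hepatocyte (4), positive acute phase (4), NF-kB (4) and adipocyte lists (4).

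The interaction asks whether the change across calving differed between diets. No gene passed by limma. The log2 change of IGF1 was higher in LP by 1.97 (SE 0.515) and that of THRSP by 1.92 (SE 0.64), each in 5 of 5 LP cows against the AP mean, without passing (adjusted p = 1 for both). Camera called 16 of 38 lists, 4 upward and 12 downward, 0 with an estimated correlation or fry, 8 without the postpartum array of cow C (5 upward and 3 downward), 9 without cow C and 9 without cow G. Fibroblast (16 of 16 positive, camera adjusted p = 1.65e-06) and skeletal muscle markers (13 of 13, 2.03e-06) led upward, and cell cycle (34 of 38 negative, 6.97e-06) and positive acute phase genes (26 of 31, 1.77e-05) led downward, each with adjusted p = 0.633 with an estimated correlation. Without that array, cell cycle (3.7e-10), positive acute phase genes (0.00207) and macrophage markers (3.85e-05) were lower, and fibroblast (1.24e-05) and skeletal muscle markers (0.00737) and cholesterol synthesis (1.24e-05), fatty acid synthesis (0.0191) and xenobiotic genes (0.0308) were higher. In that fit the adjusted p = 0.826 with an estimated correlation for skeletal muscle and 0.785 for the other 7. Skeletal muscle markers were not called when the antepartum array of cow F was left out as well (0.872). Urea cycle (0.672), complement (0.571), oxidative phosphorylation (0.678), fatty acid oxidation (0.343), gluconeogenesis (0.377), lipoprotein (0.434), purine (0.224), interferon (0.571), T or NK cell (0.224) and cholangiocyte lists (0.0695) lost their calls without the array of cow C. Without cow G and with the array of cow C, the cell cycle list had a camera adjusted p of 0.0451. Fatty acid synthesis (up to 0.401, without cow B) and macrophage lists (up to 0.13, without cow G) each kept the call in 6 of 10 fits with 1 cow left out. The values without an array come from a choice made after seeing the data. Adipocyte markers had 0.0538 by camera and 0.0361 with the animal as a block. Without the block they were not called with an estimated correlation either. Phosphate (0.605) and vitamin D and calcium genes (0.768) were not shifted.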

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

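The tests of tissue admixture and of a lower hepatocyte share, that of a diet effect that ended, and that of the cow C array as the source of the smaller LP change were chosen after the result was seen. The rule that SYT4 needs both split counts was also set after the result was seen.

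The postpartum LP array of cow C was far from the other 4 of its group for adipocyte (gap over range 0.925), skeletal muscle (0.865), endothelial (0.827) and fibroblast markers (0.736), which were highest there, and for oxidative phosphorylation (0.824), complement (0.805) and urea cycle genes (0.763), which were lowest. A lower share of hepatocytes alone would raise all other cell types alike. Fat, fibroblast and muscle markers lay 2.583 log2 further above the other arrays than the remaining non-hepatocyte markers did (SD of those 1.117). These lists were pooled after their high scores here were seen, so the gap is only weak evidence against a lower hepatocyte share alone. Among the remaining lists, the median excess ran from -0.156 for T or NK cell to 0.752 for endothelial markers. Fat, connective and muscle tissue in the sample is a candidate explanation. A share of 0.861 of these markers (31 of 36) was highest in this array. The same held for 14.6% of all genes, 69.2% of endothelial and 42.9% of macrophage markers. The choice of lists made a high share likely, so the share is no separate test. COL1A1 was at 13.25 (highest other array 8.77), ADIPOQ at 11.26 (4.95) and FABP4 at 11.04 (4.16). No other explanation was tested, and a lesion of the liver itself stays open.

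SYT4 was higher in LP by as much after calving as before (interaction 0.002 log2, SE 0.165). The interval of the interaction (-0.341 to 0.346) excludes a loss of the 0.83 difference. SYT4 was taken up because it passed at both times, a choice that favours an interaction near 0. The interval is therefore only weak evidence against a diet effect that ended with the shared ration. A lasting difference between animals that fell on the diets by chance could not be told apart from a diet effect that lasted. Of 100 splits of the animals 3 gave some gene a p as low, which by the bound written in advance would have excluded chance, but 8 gave at least 1 called gene, so that bound was judged too narrow after the result was seen. Antepartum alone only the real split gave a called gene, so that the split counts conflict, and a lasting diet effect stays open too.

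Among the genes called in AP, the change across calving was smaller in LP than in AP (median ratio 0.517). Leaving out the array of cow C moved this ratio only to 0.539, which is weak evidence against that array as the cause, as a choice of genes by their AP values could hold the ratio low in either fit. For that choice itself, as many genes chosen in LP had a median AP over LP ratio of 0.824, which is between the bounds set for either answer. Differences between animals stay open, since each animal's slope on the mean change of the other 9 was 0.395 ± 0.355 (SD, n = 5) in LP and 0.78 ± 0.129 in AP, with p = 0.0794 by an exact permutation test over 252 regroupings. A diet effect on the size of the change stays open too.

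Other single arrays were far from the rest of their group, with the gap over range above 0.71. In all 21 of 216 groups were, against 10.8 by chance, and 7 of these were the cow C array. Cow F was highest antepartum for ketone body genes (0.766) and skeletal muscle markers (0.755) and postpartum for SCGB1D (0.863), and lowest postpartum for B cell markers (0.732). Cow G was highest antepartum for fatty acid (0.713) and cholesterol synthesis (0.838), and cow H was highest postpartum for cholesterol synthesis (0.805) and RNF125 (0.819) and lowest for GPX3 (0.796). Cow A was lowest antepartum for negative acute phase genes (0.723), macrophage markers (0.72) and IGF1 (0.819), cow B for the unfolded protein response (0.785) and cow J for platelet markers (0.87).

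The change across calving differed between diets for 16 lists by camera, 0 of them with an estimated correlation. Downward in LP were cell cycle (adjusted p = 6.97e-06), positive acute phase (1.77e-05), urea cycle (0.000384), complement (0.000384), oxidative phosphorylation (0.000384), fatty acid oxidation (0.00116), gluconeogenesis (0.00259), lipoprotein (0.00548), macrophage (0.0184), purine (0.0228), T or NK cell (0.0398) and interferon lists (0.0481). Upward were fibroblast (1.65e-06), skeletal muscle (2.03e-06), fatty acid synthesis (0.028) and cholangiocyte lists (0.0372). Of these 16, 6 kept the call without the array of cow C, namely the cell cycle, positive acute phase, macrophage, fibroblast, skeletal muscle and fatty acid synthesis lists. With 1 cow left out, fatty acid synthesis (0.401 without cow B) and macrophage calls (0.13 without cow G) were lost, and the other 4 were kept. Of these 4, the skeletal muscle call was lost when the antepartum array of cow F was left out along with that of cow C (camera adjusted p = 0.872).

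Other splits of the arrays or animals, 100 for each result with the real one included, test whether chance can be excluded. For the 300 genes changed across calving, where each split swaps the times within cows and so parts all pairs, it can (1 split as large, highest other 222). For the 1 gene of diet antepartum, SYT4, only the real split gave a call (1, highest other 0). The other diet comparisons call the same gene in the same cows, and there chance cannot be excluded. For SYT4 chance therefore stays open. For the 83 genes in AP, 1 of 100 splits was as large (highest other 2), but these mix the pairs. Only 16 splits part all pairs in AP, with 83 against a highest other of 0, which is too few for a share under 0.05. Chance cannot be excluded for the 1 gene of diet postpartum (10 as large, highest other 4) or over both times (8, highest other 2) or the 3 genes in LP (9, highest other 453). For the interaction, a real count of 0 by limma (559 unadjusted) makes all 100 splits as large (highest other 0), so that they test nothing. Nor can chance be excluded for the lists called for diet antepartum (7 as large, 12 against a highest other of 16), diet postpartum (36, 19 against 25), time (16, 17 against 23) or the interaction (22, 16 against 24). The split of LP arrays with 453 genes set the antepartum arrays of cows A, D and E and the postpartum arrays of cows C and E against the other 5, a structure of the samples whose cause was not tested. In LP too only 16 splits part all pairs, with 3 genes against a highest other of 0, too few for a share under 0.05.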

How the results depend on the processing

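The fits without single arrays, the block without cow C and the exact permutation of lists were chosen after seeing the data. No result of a gene named by the rule fixed in advance changed direction; these genes were chosen by their size or p, so this is no measure of robustness. The 10 genes named later kept theirs in all 16 fits run on them. Of the former that passed, 1194 alternatives kept the call and 200 lost it; of the others, 76 gained one. Called lists kept the call in 893 alternatives, lost it in 410 and changed direction in 9, and others gained it in 8 and changed direction in 25. Where not stated the cause was not tested.

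With only the groups compared, genes were 0 for diet antepartum, 0 for diet postpartum, 412 in AP and 0 in LP. Array weights gave 654 for time and 613 in AP, and leaving out the dimmer 50% of genes 151 in AP. With the animal as a replicate block time had 381 genes, 265 of them among the 300, and AP had 126, 64 of them among the 83. Beyond the calls given in the results, no other call of a list, or of a gene named by the rule fixed in advance, changed with the block. Without the cow C array there were 546 genes for time, 287 in AP, 9 in LP, 5 lists for diet postpartum and 8 for the interaction. Without both arrays with muscle markers, genes were 0 for diet postpartum and 0 over both times (there without cows C and F altogether), 159 in AP and 5 in LP, with 2 and 7 lists. The block without cow C gave 668, 429 and 5 genes and 9 interaction lists. An unadjusted p with 1.5-fold gave 59, 162 and 41 genes for diet antepartum, postpartum and over both times, 432 in AP, 197 in LP and 155 for the interaction. Camera with an estimated correlation, fry and the exact permutation each called 0 lists in all 4 comparisons, where limma's camera had 12, 19, 17 and 16. Exact permutation adjusted p were at least 0.0848. The smallest p it can reach is 0.00794 for the diets and the interaction. Over 38 lists it therefore had little power to call any list in these comparisons. For time it can reach 0.00195, but the lowest exact permutation p found was 0.00977, for the cell cycle and T or NK cell lists. The limit alone thus does not account for the 0 calls for time.

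Leaving out each animal gave 0 to 1 genes for diet antepartum, 0 to 2 postpartum, 0 to 1 over both times, 131 to 449 for time, 13 to 243 in AP, 0 to 6 in LP and 0 to 0 for the interaction. Lists ranged from 8 to 12, 5 to 22, 14 to 21 and 9 to 18. Of the called lists, 6 of 12 for diet antepartum, 1 of 19 postpartum, 10 of 17 for time and 4 of 16 for the interaction kept the call whichever animal was left out. SYT4 had adjusted p from 0.00083 to 0.167 antepartum, 0.00215 to 0.213 postpartum and 9.8e-05 to 0.129 over both times. Without both arrays with muscle markers its limma adjusted p was 0.067 postpartum and 0.129 over both times, where cows C and F dropped out.

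Directions turned, with camera adjusted p of the opposite direction, for diet postpartum without cow C, without its array and without both muscle arrays in oxidative phosphorylation (0.175, 0.174, 0.187), skeletal muscle (0.81, 0.815, 0.682), adipocyte (0.186, 0.189, 0.188) and phosphate lists (0.881, 0.911, 0.909). The urea cycle list for time turned in the same settings (0.0801, 0.115, 0.152) and with the animal as a block without cow C (0.0773), as did phosphate in the interaction in these 4 settings (0.332, 0.377, 0.226, 0.185). Antepartum, gluconeogenesis turned without cow B (0.711), cow H (0.911), cow I (0.863), cow J (0.826) and cow E (0.329) and by exact permutation (1), and fatty acid oxidation without cow B (0.741), cow H (0.861), cow J (0.869) and cow E (0.671). Fatty acid synthesis postpartum turned without cow B (0.557) and cow J (0.994). The vitamin D list turned in the interaction without the dimmest genes (0.915) and for time with the block without cow C (0.836). Leaving out each animal, adjusted p ranged over either direction from 0.328 to 0.911 for gluconeogenesis and 0.324 to 0.97 for fatty acid oxidation antepartum. Postpartum they ranged from 0.000467 to 0.175 for oxidative phosphorylation, 0.000654 to 0.81 for skeletal muscle, 0.0101 to 0.186 for adipocyte, 0.0193 to 0.881 for phosphate and 0.0148 to 0.994 for fatty acid synthesis lists. For the urea cycle across calving the range was 0.0801 to 0.878, and for phosphate in the interaction 0.26 to 0.934.

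No signal over background was used, so that dim genes may carry little information, and leaving out the dimmer 50% gave 399 genes for time.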

Other observations

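The 6 genes named in this part, and the comparison of the diet differences at both times, were chosen after the result was seen. Several genes of lipoprotein and glycogen metabolism changed across calving although their lists were not shifted with all arrays. Without the postpartum array of cow C the lipoprotein list was called upward (camera adjusted p = 0.0081; adjusted p = 0.245 with an estimated correlation). APOA4 rose by 1.52 log2 (SE 0.364, limma adjusted p = 0.0367), APOC2, the activator of lipoprotein lipase, by 0.67 (SE 0.128, adjusted p = 0.0096) and SCARB1, a receptor of high density lipoprotein, by 0.51 (SE 0.102, adjusted p = 0.0125). APOH fell by 0.30 (SE 0.064, adjusted p = 0.0191, and 0.0664 with the animal as a block). Of 24 lipoprotein genes 4 rose and 1 fell, and 5 and 2 did adjusted over the list alone. PPP1R3B, a glycogen-targeting phosphatase subunit, fell by 1.47 (SE 0.221, adjusted p = 0.0014), and AK4, a mitochondrial adenylate kinase, by 1.42 (SE 0.244, adjusted p = 0.00524). Of 16 fits run on each, APOA4 passed in 8 (adjusted p up to 0.128 without cow D), APOH in 10 (up to 0.0849 without cow I) and SCARB1 in 14 (up to 0.0562 without cow I), and APOC2, PPP1R3B and AK4 in all. Of 34 glycolysis and glycogen genes 0 rose and 2 fell by limma, and 3 and 5 did adjusted over the list alone.

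Diet differences before and after calving, on the same cows, correlated across genes with r = 0.099, and genes are not independent replicates. Over all 126 splits of the animals r ran from -0.199 to 0.388 with a median of 0.156, and 92 were as high.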
